A study of Oryctolagus cuniculus and Homo sapiens with 66 samples.

How the data were processed

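Gene expression was measured on an Affymetrix array whose probe sets are annotated to human genes, hybridised with RNA from 57 blood samples of 46 rabbits and from 9 samples of human peripheral blood mononuclear cells (PBMC). Per the labels' protocols, rabbit leukocytes were collected after sedimentation of red cells with gelatin, total RNA was extracted with TRIzol and columns, and the RNA was amplified in repeated rounds of cDNA synthesis and in vitro transcription before biotin labelling. The rabbits came from a pedigreed colony that was not inbred, and animals of later cohorts were related to those of earlier ones, so that rabbits were separate animals but not unrelated.

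The deposited values, a single one per probe set and array, are on a log scale that is taken here as log2, since the log base is not given in the sources used here and a natural log would put the highest values above the range of an array scanner. The submitters' processing notes name MAS5 and Partek, with no version and no role. The sorted values of all arrays, human and rabbit, formed 1 distinct profile to 2 decimals, so the deposited log2 values had already been brought to a common distribution over human and rabbit arrays together. The rabbit and human values are therefore relative levels within an array, and a shift shared by most probe sets of an array is not visible in them. Scanner intensities were not used here.

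Of 12625 probe sets, 67 controls were left out and 12558 were tested. The platform annotation named 1 gene for 10943 probe sets, several for 545 and none for 1070. Gene names are given only for probe sets with 1 gene, and they are the human genes the probes were designed for. Of the 8226 genes so named, 7441 symbols were also found in the rabbit annotation of assembly mOryCun1.1, which was used only for this count. A rabbit transcript that differs in sequence from the human probes gives a weak signal. The 23 control probe sets designed to have no target had a median of 6.80 in the rabbit arrays and a 95th percentile of 7.72, and 4820 probe sets (38.4%) had a rabbit mean above that percentile. The number of arrays limits the precision of every value.

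Arrays were grouped by the immunogen and backbone in the labels. SM and GR are the immunizing peptides, and backbone stands for the carrier alone in the same adjuvants. MAP4 and MAP8 are branched lysine carriers for the peptides. All MAP4 rabbits belonged to cohort 2, and the MAP8 rabbits to cohorts 1, 3 and 4, so carrier, cohort and number of boosts cannot be told apart. The rabbits' aliases fall into series (letters, S, 3.x, 4.x and whole numbers) that coincide with the cohort for every immunized rabbit. The series was used as a factor where immunized and unimmunized rabbits were compared, because it is the label that both kinds of sample share. Within the letter series all immunized rabbits were of cohort 1 and both unimmunized ones of cohort 2, and within the 3.x series the immunized rabbits were of cohort 3 and the unimmunized ones of cohorts 2 and 4, so that immunization and cohort cannot be told apart in these series. Of the unimmunized arrays in this comparison, 6 of 12 came from rabbits that also gave an immunized array in it, and in the 4.x series 4 of 5 did, while the fifth came from a PBS rabbit. Samples of the 3 rabbits given phosphate-buffered saline (PBS) carry the carrier name MAP8 in a label, while the labels' protocols state that they received PBS only, and the protocols were followed.

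Linear models were fitted to log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with the package data.table (version 1.17.8) for input. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 12558 probe sets, and every adjusted p for a gene below is limma's. SM, GR and backbone were compared among 40 rabbits with cohort as a factor, and again with a coefficient per peptide and carrier. Immunized and unimmunized rabbits were compared in 42 arrays of the letter, 3.x and 4.x series with series as a factor. Samples of the 10 rabbits taken before and after immunization were compared with the animal as a block. PBS was compared with unimmunized and with backbone rabbits in the 21 arrays of the 4.x series. The 9 human samples were compared with the 9 rabbit samples that the labels mark for that purpose. The pairing of samples by animal comes from the rabbit identity in the labels, whereas the replicate numbers of the groups only name samples.

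Gene lists were fixed with the design, before the data were examined, and tested with limma's camera at a preset correlation between genes of 0.01, each gene by its probe set with the highest rabbit mean, with Benjamini-Hochberg adjustment over the 26 lists. They cover type I interferon, interferon-gamma and antigen presentation, neutrophil, monocyte, B cell, plasma cell, T cell, NK cell, platelet, erythroid and a dendritic cell, eosinophil, basophil and mast cell set. They also cover complement, Toll-like receptor and NF-kB signalling, cytokines and chemokines, the TNF superfamily, B cell receptor signalling, costimulation, proteasome, ribosomal proteins, oxidative phosphorylation, cell cycle, apoptosis, heat shock and unfolded protein response, spliceosomal and Ro/La autoantigens, the NMDA receptor and its scaffold, and early-response genes. An estimated correlation was the alternative, and no call of a rabbit comparison held with it.

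The genes named were chosen by a rule fixed at the same time. It takes up to 10 rises and 10 falls among passing probe sets with 1 gene and a mean above the median of all probe sets, the 3 smallest p-values in each direction where fewer than 6 passed, the 2 members of each list with the smallest p-values in each direction, and SNRPB and GRIN2B, the source genes of the peptides. Genes named outside that rule were chosen after their values were seen, and they are marked as such.

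The alternatives fixed with the design were quantile normalization within a fit, median centring, the upper part of probe sets by mean, log2(value + 16), no intensity trend, sex as a factor, the replicate number as a block, array weights, cohort left out, the MAP8 GR rabbit with 7 boosts left out, a separate fit per carrier, the rabbit group or a random animal block (duplicateCorrelation) for the immunization comparison, the alias series as a further factor for the pairs, and each array of a small group left out. Alternatives added after the data were seen left out the letter series or the 4 arrays with a median correlation under 0.9, kept the probe sets above the absent controls, used the 4.x series alone, left out each pair, took the animal as a random block without the letter series and within the 4.x series, and centred the human and rabbit arrays on the mean of their 9 bacterial spike-in probe sets. The comparisons within the 4.x series of SM, GR and backbone, and of immunized with PBS rabbits, were also added then.

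The fits were tested on simulated data with the means and residual spread of each comparison and known differences in 100 probe sets per size. Of differences of 0.5, 89% were recovered for SM against backbone over both carriers, 55% within MAP8 and 47% within MAP4, and 99% for immunized against unimmunized rabbits. Of differences of 1, at least 96% were recovered in each of these comparisons. For the interaction of SM with carrier, 25% were recovered at 0.5 and 76% at 1. The simulated errors were independent, normal and of equal spread in every array of a fit. They did not include the poorer agreement of some arrays or rabbits sampled more than once. These shares therefore do not measure what the real arrays could detect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.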

Results

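Leukocyte RNA was profiled in rabbits immunized with peptides of lupus autoantigens, as a model of systemic lupus erythematosus. The SM peptide comes from the Sm B/B′ protein of the spliceosome and the GR peptide from an extracellular part of NMDA receptor subunit 2b, and each was presented on a branched carrier, MAP4 or MAP8, in Freund's adjuvants. The 57 rabbit arrays comprised 5 SM, 4 GR and 4 backbone rabbits on MAP4, 9 SM, 13 GR and 5 backbone rabbits on MAP8, 3 rabbits injected with PBS and 14 samples of unimmunized rabbits. Male rabbits gave 31 of the arrays and female rabbits 26. A further 9 arrays held human PBMC. The RNA of the source gene of the SM peptide, SNRPB, was measured well above the absent controls (rabbit mean 10.36), whereas GRIN2B, the source gene of the GR peptide, was not (6.70).

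The letter series stood apart in its agreement with the other rabbit arrays. Its 12 arrays had median correlations from 0.746 to 0.979 with the rest, compared with 0.974 to 0.983 for the 21 arrays of the 4.x series and 0.934 to 0.976 for the 9 of the 3.x series. The 4 arrays below 0.9 were MAP8 GR replicates 1 (0.847), 11 (0.748) and 12 (0.86) and MAP8 backbone replicate 1 (0.746), all in the letter series. The highest correlation between rabbit arrays was 0.995, and no arrays held identical values.

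**Figure D1:**
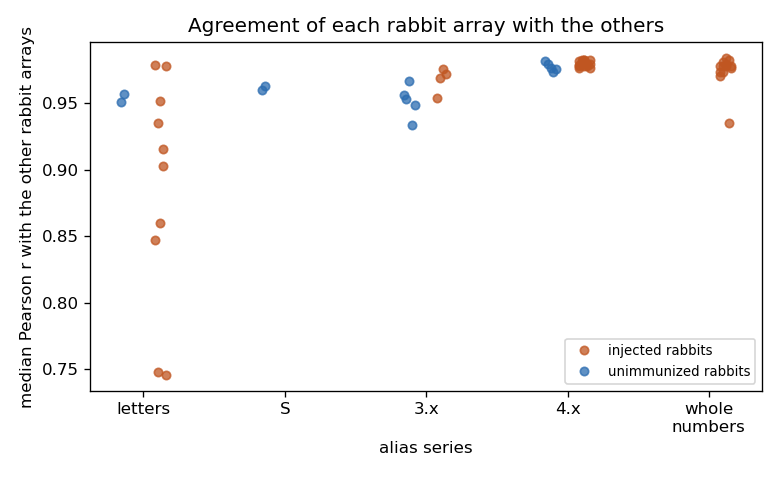
Median Pearson correlation of each rabbit array with the other rabbit arrays (vertical axis) by alias series (horizontal axis), each point an array of an injected (orange) or unimmunized (blue) rabbit. The letter series spans 0.746 to 0.979 and the 4.x series 0.974 to 0.983.

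The comparison of MAP8-immunized rabbits (SM, GR and backbone, n = 27) with unimmunized rabbits (n = 12) asks what immunization with adjuvant did to circulating leukocytes. KDM6B, a histone H3K27 demethylase induced in activated macrophages, rose by 0.56 on the log2 scale (SE 0.11, adjusted p = 0.0237) in the fit with series as a factor. Its means over all series, without that adjustment, were 9.98 ± 0.19 (SD, n = 12) and 10.37 ± 0.48 (SD, n = 27). Its other probe set differed by 0.42 (SE 0.11, adjusted p = 0.346). A probe set without a gene name was the other of the 2 that passed. An unadjusted p under 0.05 was found for 637, where chance alone gives 628 on average. PICALM, a clathrin adaptor of endocytosis, differed by 0.78 (SE 0.16, adjusted p = 0.0566), GAB2, an adaptor of growth factor and Fc receptor signalling, by 0.53 (SE 0.11, adjusted p = 0.0748), and NOS2, the inducible nitric oxide synthase, by -0.46 (SE 0.11, adjusted p = 0.183). No list passed (smallest camera adjusted p = 0.54), and 0 of the 671 list memberships passed. The count fell to 1 without MAP8 backbone replicate 2, 4 or 5, where KDM6B no longer passed, and rose to 5 without replicate 1. KDM6B thus passed in 2 of the 5 runs that left out 1 array (adjusted p 0.0104 to 0.105).

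Without the letter series, an alternative chosen after the arrays had been seen, 130 probe sets passed (92 higher and 38 lower in 17 immunized than in 10 unimmunized rabbits). The macrophage chemokine CCL4 rose by 0.94 (SE 0.15), PICALM by 0.92 (SE 0.13), CEBPD, a transcription factor of the acute-phase and granulocyte response, by 0.81 (SE 0.16), and 1 of the 3 probe sets of the angiogenic factor VEGFA by 0.81 (SE 0.14). The other probe sets of VEGFA differed by 0.05 (SE 0.07) and 0.04 (SE 0.03) and did not pass. CITED2, a hypoxia-inducible co-regulator, rose by 0.73 (SE 0.14), the metalloproteinase inhibitor TIMP2 by 0.63 (SE 0.13), GAB2 by 0.60 (SE 0.09), SAT1, an enzyme of polyamine breakdown, by 0.58 (SE 0.12), KDM6B by 0.57 (SE 0.09) and the transcription factor MAF by 0.57 (SE 0.14). MEF2C, a transcription factor of B cells and other lineages, fell by 0.65 (SE 0.14), PRKCB, a protein kinase C of B cell receptor signalling, by 0.58 (SE 0.12), the nuclear co-repressor NRIP1 by 0.56 (SE 0.12), TAF15 by 0.45 (SE 0.11), UBE2E3 by 0.44 (SE 0.10) and NOS2 by 0.38 (SE 0.09). MXI1, COPS2, NFYB and GRB2 fell by 0.27 to 0.31. The rabbit means of SAT1, MAF, NRIP1 and COPS2 did not exceed the absent controls. Both probe sets that passed with all series were among the 130.

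Among the cell type lists in the same fit, 3 of 31 neutrophil genes rose, namely S100A9 by 0.58 (SE 0.07) and S100A12 by 0.17 (SE 0.04), which encode calcium-binding alarmins, and, chosen after its value was seen, the integrin ITGB2 by 0.15 (SE 0.04). Of 22 monocyte genes, CD68 rose by 0.16 (SE 0.04) and TYROBP, an adaptor of myeloid receptors, by 0.22 (SE 0.04). Of 20 B cell genes, MS4A1, which encodes CD20, fell by 0.19 (SE 0.04) and the adaptor BLNK by 0.32 (SE 0.08), and 18 did not pass. Among 21 B cell receptor signalling genes, 1 rose (FYN by 0.37, SE 0.09) and 2 fell. TRIM21, which encodes the Ro52 autoantigen, rose by 0.18 (SE 0.04) as 1 of 21 spliceosomal and Ro/La genes, whereas 0 of 28 type I interferon genes and 0 of 14 plasma cell genes passed. Adjusted over the list alone, 3 neutrophil genes, 3 monocyte genes, 3 T cell genes and 1 B cell gene rose, and 2 B cell genes, 1 T cell gene and 4 B cell receptor signalling genes fell. None of the 26 lists passed camera as a whole (smallest adjusted p = 0.33). The rabbit means of S100A9, MS4A1, BLNK and TRIM21 did not exceed the absent controls.

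**Figure D2:**
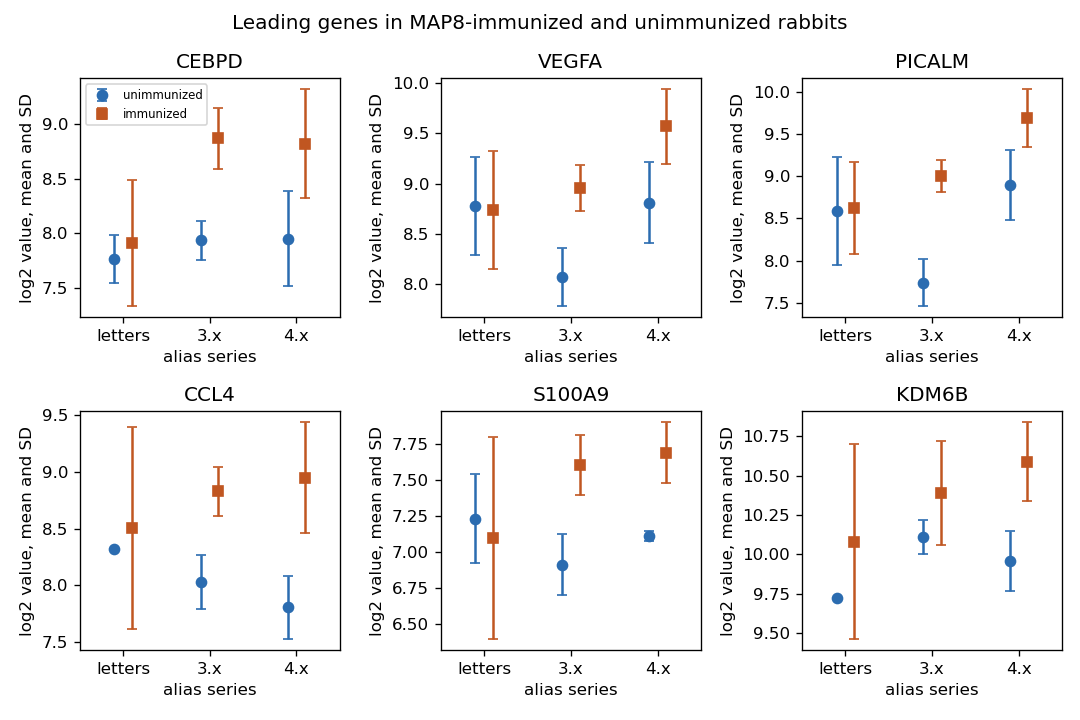
Mean log2 value (vertical axis) with SD of immunized (orange squares) and unimmunized rabbits (blue circles) in the letter (n = 10 and 2), 3.x (n = 4 and 5) and 4.x series (n = 13 and 5) for 6 leading genes. CEBPD differs by 0.94 in the 3.x and 0.87 in the 4.x series and by 0.15 in the letter series.

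Within the series, CEBPD was higher in immunized rabbits by 0.94 in the 3.x, 0.87 in the 4.x and 0.15 in the letter series, VEGFA by 0.89, 0.76 and -0.04, PICALM by 1.27, 0.80 and 0.03, and S100A9 by 0.69, 0.58 and -0.14. In the 4.x series alone, 174 probe sets passed (88 higher and 86 lower, 13 against 5 arrays). The count was 31 to 177 when single arrays were left out, with 31 without unimmunized replicate 12, the sample of a PBS rabbit. The mean of CEBPD there was 8.58 ± 0.58 (SD, n = 4) with SM, 9.08 ± 0.46 (SD, n = 6) with GR and 8.63 ± 0.30 (SD, n = 3) with backbone, compared with 7.95 ± 0.44 (SD, n = 5) without immunization and 7.84 ± 0.28 (SD, n = 3) with PBS. For PICALM the means were 9.48 ± 0.24, 9.83 ± 0.42 and 9.69 ± 0.01 with SM, GR and backbone, 8.90 ± 0.41 without immunization and 9.28 ± 0.08 with PBS (SD, same n). Of the 88 probe sets that rose, 69 were also higher in the 3.x series, and of the 86 that fell, 36 were also lower.

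Blood drawn before and after immunization from the same 10 rabbits (5 given backbone, 3 GR and 2 SM) removes differences between animals. It does not remove differences between array series, since only 4 pairs had both arrays in the same series, the 4.x. The samples after immunization were also the later ones of each rabbit, so time and immunization cannot be told apart in the pairs. CEBPD rose by 1.08 (SE 0.11, adjusted p = 0.00301), from 7.75 ± 0.42 to 8.83 ± 0.39 (SD, n = 10), and was higher afterwards in 10 of 10 rabbits. One probe set of VEGFA rose by 1.12 (SE 0.17, adjusted p = 0.0495) and GAB2 by 0.67 (SE 0.09, adjusted p = 0.0183), each higher in 9 of 10 rabbits. When single pairs were left out, VEGFA and GAB2 each passed in only 2 of 10 runs. The remaining 2 probe sets of VEGFA differed by 0.09 (SE 0.07, adjusted p = 0.646) and 0.05 (SE 0.06, adjusted p = 0.758). MARCKSL1, an actin-regulating substrate of protein kinase C, rose by 0.46 (SE 0.05, adjusted p = 0.00433), with 10 of 10 rabbits higher. Its means in the 4.x series were 10.41 ± 0.14 (SD, n = 5) without immunization and 10.62 ± 0.08 (SD, n = 3) with PBS. With SM, GR and backbone they were 10.68 ± 0.16 (n = 4), 10.94 ± 0.11 (n = 6) and 10.92 ± 0.10 (n = 3), so PBS rabbits also lay above unimmunized ones. No probe set fell past the threshold, and 1360 had an unadjusted p under 0.05. Genes that led the comparison of immunized and unimmunized rabbits did not pass here: KDM6B differed by 0.39 (SE 0.11, adjusted p = 0.34, higher in 8 of 10 rabbits) and PICALM by 0.78 (SE 0.24, adjusted p = 0.352, 8 of 10). CCL4 differed by 0.58 (SE 0.19, adjusted p = 0.352, 7 of 10) and S100A9 by 0.32 (SE 0.13, adjusted p = 0.419, 8 of 10). The lower values of S100A9 (-0.48 and -0.23) and CCL4 (-0.37, -0.36 and -0.02) were all in rabbits given the MAP4 backbone. Their earlier arrays belong to the S or letter series and their later ones to the whole-number series, so carrier and series cannot be told apart there. The kinase FYN differed by 0.75 (SE 0.13, adjusted p = 0.0999) and SNRPB by 0.29 (SE 0.10, adjusted p = 0.378).

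**Figure D3:**
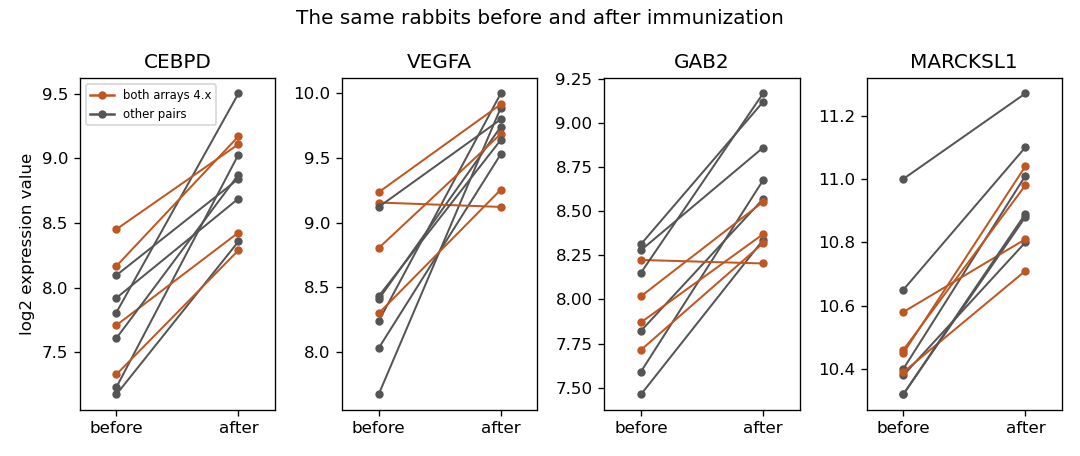
Log2 value (vertical axis) before and after immunization (horizontal axis) for the 4 genes that passed, each line a rabbit, with orange lines for the 4 rabbits whose arrays both belong to the 4.x series and grey lines for the other pairs. CEBPD and MARCKSL1 were higher afterwards in 10 of 10 rabbits, and VEGFA and GAB2 in 9.

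No list passed camera over the pairs. The early-response list came closest (median 0.08, adjusted p = 0.06, and 0.24 with an estimated correlation), and 2 of its 18 members rose adjusted over the list alone, with KLF6 at 0.55 (SE 0.13) and NR4A2 at 0.37 (SE 0.09). Of 20 B cell genes, 2 were lower adjusted over the list alone, and BLNK differed by -0.35 (SE 0.07, adjusted p = 0.221 over all probe sets). Within the 4 pairs whose arrays both belong to the 4.x series, CEBPD differed by 0.84 ± 0.18 and MARCKSL1 by 0.42 ± 0.17 (SD, n = 4), higher in 4 of 4, and VEGFA by 0.62 ± 0.45 and GAB2 by 0.40 ± 0.29, each higher in 3 of 4. With the alias series as a further factor 0 passed (443 with unadjusted p under 0.05), and without the pairs of the letter series 0 passed in limma (637 with unadjusted p under 0.05). Over these and the other alternatives for the pairs, apart from runs without single pairs, CEBPD differed by 0.84 to 1.21 and MARCKSL1 by 0.42 to 0.46. VEGFA differed by 0.62 to 1.16 and GAB2 by 0.405 to 0.673.

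Rabbits injected with PBS received neither antigen nor adjuvant, and their comparison asks what injection alone does. All 3 were male and shared the first part of their rabbit identity, which no immunized rabbit of the 4.x series carried and which 1 of the 5 unimmunized arrays had. The labels do not say what it marks, so injection and a possible common descent cannot be told apart in any comparison with PBS below. THBS3, a member of the thrombospondin family of matrix proteins, was the 1 probe set that passed against unimmunized rabbits, and it fell by 0.33 (SE 0.05, adjusted p = 0.0192), from 8.18 ± 0.07 (SD, n = 5) to 7.85 ± 0.04 (SD, n = 3). It did not pass without any 1 of the 3 PBS arrays or of unimmunized replicates 8, 10 and 11. Against PBS, the MAP8 backbone in adjuvant (n = 3) gave 0 passing probe sets in limma, with 697 at an unadjusted p under 0.05. S100A9 differed by 0.65 (SE 0.12, adjusted p = 0.157) and the iron and porphyrin transporter ABCB6 by 0.34 (SE 0.06, adjusted p = 0.128). The neutrophil list was higher with backbone (25 of 31 genes above 0, median 0.04, camera adjusted p = 0.036, adjusted p = 0.15 with an estimated correlation), although 0 of its members passed over all probe sets and 2 rose adjusted over the list alone. When SM, GR and backbone rabbits of the 4.x series were pooled against PBS, a comparison chosen after the data were seen, S100A9 was the 1 probe set that passed, and it rose by 0.64 (SE 0.10, adjusted p = 0.017). The rabbit means of S100A9 and ABCB6 did not exceed the absent controls.

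The central question of the design is how peptide immunization differs from carrier and adjuvant alone. For SM over both carriers (14 against 9 rabbits), the ribosomal protein list was higher (36 of 46 genes above 0, median 0.11, camera adjusted p = 0.0064, adjusted p = 0.89 with an estimated correlation), with RPS15A at 0.39 (SE 0.15) and RPL7 at 0.55 (SE 0.23) and RPS28 at -0.31 (SE 0.11). The mean of RPS15A did not exceed the absent controls. The median difference of the ribosomal protein list was 0.32 in cohort 1, which had 1 backbone array, 0.08 in cohort 2 and -0.02 in cohort 4. Without the letter series it did not pass (adjusted p = 0.17, range over the alternatives 0.0085 to 0.89), while oxidative phosphorylation did (adjusted p = 0.042, adjusted p = 0.41 with an estimated correlation). TNRC6B, a protein of microRNA silencing, differed by 0.38 (SE 0.09, adjusted p = 0.348) and SOCS3, a feedback inhibitor of cytokine signalling, by 0.35 (SE 0.10, adjusted p = 0.348). In limma 0 probe sets passed, and 1784 had an unadjusted p under 0.05. SNRPB differed by 0.04 (SE 0.11) and GRIN2B by 0.09 (SE 0.09).

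Within MAP8 (9 SM against 5 backbone rabbits) 0 probe sets passed in limma and 3359 had an unadjusted p under 0.05, the highest number of the comparisons among SM, GR and backbone. CLDN3, a tight junction protein, differed by 0.65 (SE 0.15), the centriole protein ODF2 by 0.74 (SE 0.18) and the GTPase RAC1 by -0.60 (SE 0.15), each with an adjusted p of 0.0852. Of 14 plasma cell genes, 2 were higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.23). Without MAP8 GR replicate 13, the rabbit with 7 boosts, 1513 probe sets passed (719 higher and 794 lower), and without MAP8 backbone replicate 1, the only backbone array of cohort 1, 0 passed and 233 had an unadjusted p under 0.05.

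Within the 4.x series, where SM (n = 4), GR (n = 6) and backbone (n = 3) arrays correlated closely, 11 probe sets differed between SM and backbone in a comparison added after the data were seen. CLASP2, a microtubule-stabilizing protein, rose by 0.78 (SE 0.13, adjusted p = 0.0278), the translation factor EIF5B by 0.85 (SE 0.15, adjusted p = 0.0278), and, named after their values were seen, BTN3A1, a butyrophilin recognised by gamma-delta T cells, by 0.54 (SE 0.08, adjusted p = 0.0238) and TAF5L, a subunit of histone acetyltransferase complexes, by 0.53 (SE 0.09, adjusted p = 0.0278). ARHGAP1, THBS3 and a probe set without a gene name rose by 0.27 to 0.40, and ACTB, beta-actin, fell by 0.66 (SE 0.12), EIF4G2 by 0.44 (SE 0.08), the erythroid membrane protein ANK1 by 0.42 (SE 0.08) and CGGBP1, also named after its value was seen, by 0.39 (SE 0.07). The means of EIF5B, BTN3A1, TAF5L and CGGBP1 did not exceed the absent controls. Of the 11, 5 had the same direction in cohort 1 and 6 in cohort 2. The count ranged from 0 to 22 when single arrays were left out, and it was 0 with sex as a factor (1398 with an unadjusted p under 0.05).

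On MAP4 (5 SM against 4 backbone rabbits) ribosomal proteins (36 of 46 genes above 0, median 0.08, camera adjusted p = 3.1e-05), oxidative phosphorylation (40 of 53, median 0.05, adjusted p = 0.00070) and the proteasome (18 of 29, median 0.06, adjusted p = 0.00074) were higher with SM, and each had an adjusted p = 0.28 with an estimated correlation. PSMD14, the deubiquitinase of the proteasome lid, differed by 0.43 (SE 0.17), and COX6C, a subunit of cytochrome c oxidase, by 0.21 (SE 0.10). The means of PSMD14, COX6C and MAF did not exceed the absent controls. MAF differed by 1.06 (SE 0.24, adjusted p = 1) and TNRC6B by 0.49 (SE 0.14, adjusted p = 1). In limma 0 probe sets passed and 50 had an unadjusted p under 0.05. The spread in the MAP4 tests was estimated over all 40 rabbits of the fit, the letter series included.

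For GR against backbone over both carriers (17 against 9 rabbits), COPS2, a subunit of the COP9 signalosome, differed by 0.30 (SE 0.11), the glutamate transporter SLC1A2 by 0.34 (SE 0.13) and the neutrophil alarmin S100A8 by 0.17 (SE 0.06), each with an adjusted p of 1. For COPS2 and S100A8 the mean did not exceed the absent controls. In limma 0 probe sets passed and 109 had an unadjusted p under 0.05, fewer than the 628 that chance gives on average. No list passed with all series, and without the letter series the proteasome did (adjusted p = 0.017, adjusted p = 0.70 with an estimated correlation). Within MAP8 (13 against 5) the homeobox gene HOXC6 differed by 0.65 (SE 0.18, adjusted p = 0.948) and creatine kinase CKB by -0.27 (SE 0.08, adjusted p = 0.948), with 0 passing and 371 at an unadjusted p under 0.05. On MAP4 (4 against 4) the proteasome list was higher with GR (22 of 29 genes above 0, median 0.05, camera adjusted p = 0.0098, adjusted p = 0.80 with an estimated correlation). This call was lost without the letter series (camera adjusted p = 0.053, range over the alternatives 0.013 to 0.80). That series holds no MAP4 array, so only the spread estimated over the whole fit changed. AMD1, an enzyme of polyamine synthesis, differed by 0.67 (SE 0.25, adjusted p = 1), with 0 passing in limma and 42 at an unadjusted p under 0.05. In the 4.x series 0 probe sets passed between GR and backbone in limma and 647 had an unadjusted p under 0.05.

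The peptides were also compared with each other. Over both carriers (14 SM against 17 GR rabbits) ribosomal proteins were higher with SM (38 of 46 genes above 0, median 0.10, camera adjusted p = 0.0067, adjusted p = 0.90 with an estimated correlation), with median differences of 0.23, 0.12 and -0.04 in cohorts 1, 2 and 4. Without the letter series it did not pass (adjusted p = 0.27, range over the alternatives 0.012 to 0.90). The chemokine CX3CL1 differed by -0.27 (SE 0.07), the translation factor EEF1D by 0.37 (SE 0.10) and the nuclear receptor coactivator NCOA1 by 0.42 (SE 0.11), each with an adjusted p of 0.362. The mean of CX3CL1 did not exceed the absent controls. In limma 0 passed and 1636 had an unadjusted p under 0.05. In the 4.x series 5 probe sets passed (4 SM against 6 GR arrays). No SM rabbit there shared the first part of its identity with a GR rabbit, so peptide and a possible common descent cannot be told apart. The growth arrest gene GADD45A fell by 0.86 (SE 0.14, adjusted p = 0.0306), and, named after their values were seen, UGP2, an enzyme of glycogen synthesis, by 0.58 (SE 0.10, adjusted p = 0.0306) and CGGBP1 by 0.34 (SE 0.06), and so did the protease CTSC, which activates granule serine proteases, by 0.26 (SE 0.05), while EIF5B rose by 0.73 (SE 0.13). The rabbit means of GADD45A, UGP2, CGGBP1 and EIF5B, 4 of these 5, did not exceed the absent controls. In cohorts 1 and 2, GADD45A (0.12 and 0.03) and CTSC (0.45 and 0.09) were instead higher with SM than with GR. UGP2 and CGGBP1 were lower in both of these cohorts, and EIF5B was lower in cohort 1 (-0.12) and higher in cohort 2 (0.09). The proteasome list was lower with SM in the 4.x series (5 of 29 genes above 0, median -0.07, camera adjusted p = 4.9e-06, adjusted p = 0.054 with an estimated correlation), with 3 members lower adjusted over the list alone, and the antigen presentation list was lower (12 of 29 above 0, median -0.03, camera adjusted p = 0.025, adjusted p = 0.14 with an estimated correlation). In cohorts 1 and 2 the median difference was 0.085 and 0.0018 for the proteasome, and 0.04 and -0.018 for antigen presentation.

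Whether the effect of a peptide differed between the carriers was tested as an interaction. For SM, MAF differed between MAP8 and MAP4 by -1.13 (SE 0.32, adjusted p = 0.667) and CLDN3 by 0.76 (SE 0.23, adjusted p = 0.667), and in limma 0 passed with 729 at an unadjusted p under 0.05. For GR, HOXC6 differed by 0.91 (SE 0.30, adjusted p = 1), and in limma 0 passed with 101 at an unadjusted p under 0.05. No list passed in either interaction with all series. Without the letter series, where all MAP8 SM arrays left were of cohort 4, the SM effect was lower on MAP8 for the proteasome (adjusted p = 0.00032, adjusted p = 0.19 with an estimated correlation) and ribosomal proteins (adjusted p = 0.0080, adjusted p = 0.60 with an estimated correlation). The median SM minus backbone difference of the proteasome was 0.06 in cohort 1, -0.05 in cohort 4 and 0.06 in cohort 2, the MAP4 cohort. For ribosomal proteins it was 0.32, -0.02 and 0.08. The lower effect was thus that of cohort 4 and not shared by the MAP8 rabbits of cohort 1. The median SE was 0.19, and of simulated differences between carriers 25% for SM and 19% for GR were recovered at a size of 0.5, and 76% and 81% at 1.

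Human PBMC were compared with rabbit leukocytes to describe what the array measures in each species. CXCL8, the neutrophil chemokine interleukin 8, was higher in human samples by 4.50 (SE 0.19), RPL41 by 4.22 (SE 0.12), RPS15A by 4.17 (SE 0.07), RGS2 by 4.04 (SE 0.09), LITAF by 4.03 (SE 0.10) and NFKBIA, the inhibitor of NF-kB, by 4.02 (SE 0.06). PGK1, G0S2, UBB and NCOA4 were higher by 3.76 to 3.88. None of these 10 had a rabbit mean above the absent controls. A weak rabbit signal can come from probe mismatch, so the size of these differences does not measure a difference in RNA. UTF1 differed by -1.90 (SE 0.09), PNPLA2 by -1.81 (SE 0.16), MSI1 by -1.80 (SE 0.10), ASIP by -1.80 (SE 0.06) and IL10RB by -1.78 (SE 0.17). For UTF1, PNPLA2, MSI1, IL10RB, DENND2B, TNNT1 and FZR1 the probe set is of the r_at type, as are 3.31% of all. DENND2B differed by -1.76, which is only a bound, since it stood at the highest value of the table in all 9 rabbit arrays. COX7A2, TNNT1, FZR1 and KAZN differed by -1.71 to -1.76. These directions hold as deposited, and with spike-in centring, which moved every probe set by 1.46 alike, the 10 negative differences shrank to between -0.44 and -0.26, with UTF1 the only one still past the threshold. In all, 10332 probe sets passed, 3501 higher and 6831 lower in human samples. Across probe sets, which are not independent replicates, the human and rabbit means had a Pearson correlation of 0.688 and a Spearman correlation of 0.721. Species, cell preparation and match of the probes cannot be told apart here.

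Several immune lists were higher in the human samples at the preset correlation. With an estimated correlation 5 of 17 calls held. Given with their camera adjusted p at the preset correlation, these were interferon-gamma and antigen presentation (23 of 29 genes higher and 5 lower, adjusted p = 1.6e-07, HLA-E by 3.48), monocyte (14 of 22 higher and 7 lower, adjusted p = 0.00095, FCGR3A by 3.43, both from rabbit means not above the absent controls), ribosomal proteins (38 of 46 higher and 5 lower, adjusted p = 2.4e-12), heat shock (15 of 28 higher and 8 lower, adjusted p = 0.0055) and spliceosomal and Ro/La genes (15 of 21 higher and 2 lower, adjusted p = 0.00019). The others lost the call. For T cells 17 of 26 genes were higher (adjusted p = 0.0013, adjusted p = 0.11 with an estimated correlation), for NK cells 14 of 25 (0.00096, adjusted p = 0.12 with an estimated correlation), for neutrophils 17 of 31 (0.0046, adjusted p = 0.26 with an estimated correlation) and for platelets 9 of 16 (0.0046, adjusted p = 0.29 with an estimated correlation). For type I interferon 16 of 28 were higher (0.0030, adjusted p = 0.41 with an estimated correlation), for Toll-like receptor signalling 14 of 26 (0.0087, adjusted p = 0.11 with an estimated correlation), for cytokines 20 of 40 (0.0050, adjusted p = 0.11 with an estimated correlation) and for early-response genes 10 of 18 (0.015, adjusted p = 0.10 with an estimated correlation). The proteasome had 23 of 29 higher (2.1e-06, adjusted p = 0.076 with an estimated correlation) and oxidative phosphorylation 39 of 53 (1.5e-08, adjusted p = 0.086 with an estimated correlation). As deposited, cell cycle genes were lower (28 of 36, adjusted p = 0.015) as were genes of the NMDA receptor and its scaffold (13 of 15, adjusted p = 0.025), each with an adjusted p = 0.17 with an estimated correlation, although with spike-in centring 36 and 14 of them were higher and 0 lower in limma. The remaining 9 lists did not pass: B cell (4 of 20 higher and 11 lower), plasma cell (4 and 7 of 14), erythroid (5 and 9 of 15), the dendritic cell and granulocyte set (7 and 9 of 19), complement (7 and 19 of 29), the TNF superfamily (6 and 9 of 20), B cell receptor signalling (9 and 9 of 21), costimulation (7 and 6 of 14) and apoptosis (12 and 12 of 30). For the TNF superfamily (median -0.06) and apoptosis (median -0.05) the sign of the median was opposite to the direction of the test. With spike-in centring 0 members of any list were lower in limma.

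The control probe sets differed between the species as well. The probe set for the human Alu repeat read 12.35 ± 0.11 in human and 8.79 ± 0.08 in rabbit samples (SD, n = 9 each). All 9 bacterial spike-in probe sets were lower in the human samples, by a median of -1.42, and the 23 absent controls by a median of -0.37. With every array centred on the mean of these 9 spike-in probe sets, every difference moved by 1.46, the median from -0.20 to 1.26, and 12268 probe sets were higher and 4 lower, against 3501 higher and 6831 lower as deposited. The directions above are therefore relative to the other probe sets of an array.

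**Figure D4:**
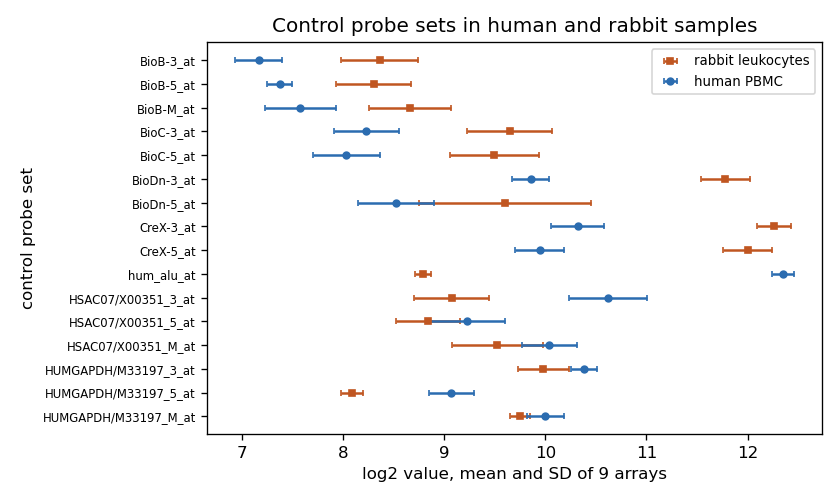
Mean log2 value with SD (horizontal axis) of control probe sets (vertical axis) in human PBMC (blue) and rabbit leukocytes (orange), n = 9 arrays each. The 9 spike-in probe sets (names starting with Bio and Cre) are lower in the human samples and the Alu probe set is higher.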

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

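The tests without the letter series and without the single backbone array, of the direction of the 4.x calls in the 3.x series, of the myeloid and B cell genes, and of normalization and neutrophil genes in human PBMC were chosen after the result was seen, as was the comparison of immunized and unimmunized rabbits within the 4.x series. Chance puts about 1 group in 20 beyond the limit for outlying samples, and 2 of the 19 groups tested lay beyond it. MAP8 backbone replicate 1 had a median correlation of 0.746 with the other rabbit arrays, while the other 4 arrays of its group lay between 0.972 and 0.983. For GAB2, the rabbit given GR whose later array is MAP8 GR replicate 10 differed by -0.0203 after immunization, while the other 9 rabbits differed by 0.50 to 1.08. For MTSS1, the difference of immunized minus unimmunized rabbits lay 1.69 higher in the letter than in the 4.x series (SE 0.37, limma adjusted p = 0.0309), as 1 of 31 probe sets for which that contrast passed. It also lay 1.12 higher in the 3.x than in the 4.x series (SE 0.34), which did not pass. MTSS1 was among 29 genes tested because they led the immunization comparisons, that of the 4.x series included. The contrast is therefore not independent of that choice and does not show a larger effect in the letter series.

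The 3359 small p-values for SM against backbone on MAP8 may follow the array that stood apart. Other splits of the rabbits within cohorts seldom gave as many (2 of 100 splits, the highest other 3529 after exchanging 2 of 14 arrays), so that chance alone can be excluded. Without the letter series 798 probe sets had an unadjusted p under 0.05, and without MAP8 backbone replicate 1 the number was 233, which is consistent with that 1 array as the source. An effect of SM shared by cohorts 1 and 4 stays open, since 59% of the 500 leading probe sets of the letter series had the same direction in the 4.x series and other splits reached 69.6%. With 1 backbone array in cohort 1, array quality and peptide cannot be told apart there.

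In the 4.x series 174 probe sets differed between immunized and unimmunized rabbits, and 2 of 100 splits gave as many, the real one included. The highest other had 206, in a split that exchanged 4 of 18 arrays. These splits take arrays as separate rabbits, which most unimmunized arrays here were not, so they do not exclude chance. Of the 5 unimmunized arrays, 4 come from rabbits that also gave an immunized array, and without the fifth, unimmunized replicate 12, which comes from a PBS rabbit, 31 probe sets passed (31 to 177 over the arrays left out). Of the 174, 60.3% had the same direction in the 3.x series, where other splits reached 76.4%, with 78.4% of the rises (other splits up to 87.5%) and 41.9% of the falls (other splits up to 75.6%), so a difference particular to the 4.x arrays stays open: the immunization effect differed between the 3.x and 4.x series for 0 probe sets in limma (190 with an unadjusted p under 0.05), of which 28 were among the 174 and 23 among the 86 falls (median 0.03 in the 3.x and -0.27 in the 4.x series), which were chosen for their 4.x values. In the letter series 83 of the 174 had the same direction, with a median of -0.0032 signed by the 4.x direction. The effect differed between the letter and 4.x series at an unadjusted p under 0.05 in limma for 48 of the 174. Whether injection alone contributed was not decided: the mean difference from PBS in the direction of the 3.x series was 0.0281, and 11 of 100 splits gave as large a value (highest 0.0402). Of the 130 probe sets called without the letter series, PBS minus unimmunized rabbits had the same direction for 115. The median was 0.0925 for PBS and 0.225 for immunized minus unimmunized rabbits in the 4.x series. Both differences share the unimmunized arrays that entered those calls, so these values do not decide it either. Against PBS 1 probe set passed in the 4.x series. Neutrophil and monocyte genes lay above B cell genes by a median of 0.049 (2 of 100 splits as large, highest other 0.051), which is consistent with a small shift in the share of these cells, a hypothesis found on the same arrays, and an effect of immunization itself also stays open.

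In the human comparison 6831 probe sets were lower and 3501 higher. Centring on the spike-ins made 12268 of 12272 called probe sets higher (100% after rounding), compared with 33.9% as deposited, but it moved every probe set by the same 1.46, so it decides nothing about the common distribution imposed on all arrays, which stays open as a source of the lower calls. A smaller share of neutrophils in PBMC could add to it, but the neutrophil genes lay only -0.32 from the monocyte, T cell and NK cell genes (SE 0.26), which does not decide. Centring adds an error shared by all probe sets, and a lower yield of rabbit transcripts on human probes would act the same way, so it stays open. Apart from the neutrophil share no biological explanation was tested, since species and cell preparation coincide.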

How the results depend on the processing

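The settings with the animal as a random block in part of the series, without the letter series, without the 4 least correlated arrays, above the absent controls, in the 4.x series alone, without single pairs and with spike-in centring were chosen after the data were seen. Of the genes followed through the settings, none reversed its direction. They led the comparisons over both carriers, of immunized rabbits with all series, of the pairs and of PBS. The calls for SM against backbone in the 4.x series were also among them. Genes named in the other rabbit comparisons were not followed. The direction of list calls was not compared with an estimated correlation or gene means. For human against rabbit, spike-in centring moved every probe set by 1.46 alike, so that 12268 were higher and 4 lower, which says nothing about single genes or lists. Quantile normalization and median centring moved almost nothing, because the arrays already share a distribution, so they say nothing about stability. The number of arrays and the 38.4% of probe sets above the absent controls limit what could be detected. The cause of each change below was not tested, except that filters test fewer probe sets.

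Among probe sets with the higher means, 4 passed for immunized against unimmunized rabbits, 7 for the pairs and 5613 for human against rabbit. Above the absent controls the counts were 4 for immunized rabbits and 4304 for human against rabbit. With array weights, SM against backbone gave 13 over both carriers, 11 on MAP8 and 3 on MAP4, GR against backbone 1 over both and 12 on MAP8, SM against GR 2, immunized against unimmunized 338, PBS against unimmunized 6 and backbone against PBS 2. Replicate numbers did not pair samples (correlations of deviations from -0.68 to 0.41, and at most 1 number per pair of groups with its own number as best match). With the replicate block 0 passed for immunized rabbits, 0 for the pairs and 0 for PBS (552, 147 and 997 with an unadjusted p under 0.05 in limma), and 2 for SM against backbone and 69 for immunized rabbits in the 4.x series.

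Without the MAP8 GR rabbit with 7 boosts, 1513 passed for SM against backbone on MAP8, and in the 4.x series alone 11. For immunized against unimmunized rabbits, 8 passed with rabbit group as the factor, 130 without the letter series, 31 without the 4 least correlated arrays and 174 in the 4.x series. With the animal as a random block 119 passed without the letter series and 158 in the 4.x series. For the pairs, 0 passed with the alias series as a factor and 0 without the letter series (443 and 637 with an unadjusted p under 0.05 in limma). SM against backbone on MAP4 gave 1 without the letter series, which holds no MAP4 array, so only the spread estimated over the fit changed. With sex as a factor, SM against backbone in the 4.x series gave 0 (1398 with an unadjusted p under 0.05 in limma).

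Leaving out 1 array at a time gave 1 to 5 for immunized rabbits, 0 to 1 for PBS against unimmunized, 0 to 1 for backbone against PBS (1 without PBS replicate 1), 0 to 22 for SM against backbone and 31 to 177 for immunized rabbits in the 4.x series, and 0 for each comparison of peptides over both carriers, per carrier or as an interaction. GR against backbone and SM against GR within the 4.x series were not run in this way. Only arrays of groups of 5 or fewer were left out in this way, so these counts do not cover the MAP8 GR rabbit above or other arrays of larger groups. SM against backbone in the 4.x series gave 0 without MAP8 SM replicate 6 or 7 or backbone replicate 5, 3 without SM replicate 4 or backbone replicate 4, 4 without backbone replicate 3, 5 and 18 without PBS replicates 2 and 1, and 22 without SM replicate 5. Immunized rabbits in the 4.x series gave 31 without unimmunized replicate 12, 94 and 98 without replicates 10 and 11, 83 and 100 without backbone replicates 5 and 4, 103 without PBS replicate 2, and 114 and 102 without SM replicates 4 and 7. The pairs gave 2 to 12, with 12 without the pair of MAP8 GR replicate 10 and 2 without those of MAP8 GR replicates 5 and 7, MAP8 backbone replicates 3 and 4, MAP8 SM replicate 7, MAP4 SM replicate 4 or MAP4 backbone replicate 1. CEBPD and MARCKSL1 passed in 10 of 10 such runs and VEGFA and GAB2 in 2.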

Other observations

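The split test of SM against backbone within the 4.x series and the splits' counts of small p-values given here were chosen after the result was seen, and so were the comparisons without the letter series and within the 4.x series, except those of PBS with unimmunized rabbits and with backbone. In the 4.x series, immunized rabbits differed from unimmunized rabbits in members of several lists, in a comparison chosen after the data were seen. CCL4, a chemokine of macrophages and T cells, rose by 1.09 (SE 0.19), as 1 of 40 cytokine genes. Of 31 neutrophil genes 2 rose (S100A9 and S100A12) and 29 did not pass, and of 22 monocyte genes 2 rose, TYROBP by 0.23 (SE 0.05) and FCER1G, the gamma chain of Fc receptors, by 0.19 (SE 0.04). Among 21 B cell receptor signalling genes FYN rose by 0.48 (SE 0.09) and PRKCB fell by 0.73 (SE 0.15). TNFSF4, which encodes the costimulatory OX40 ligand, rose by 0.16 (SE 0.04). The rabbit means of S100A9 and FCER1G did not exceed the absent controls. Adjusted over the list alone, 4 neutrophil, 4 monocyte and 3 type I interferon genes rose and 3 B cell genes fell, and no list passed camera (smallest adjusted p = 0.43).

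For immunized against unimmunized rabbits, only the real one of 100 splits gave as many as the 2 probe sets with all series (highest other 0). The same held for the 130 without the letter series (1 of 100, highest other 12). These splits take arrays as separate rabbits, although 6 rabbits gave an array to both sides, so they do not exclude chance. For the pairs chance can be excluded (1 of 100, 4 against 1). It is not excluded for the numbers of small p-values in either comparison. As many as the 637 of the immunized comparison with all series came in 21 of 100 splits (highest other 2125). For the 1360 of the pairs it was 18 of 100 (highest other 3258). For human against rabbit samples chance can be excluded (1 of 100), and the highest other split, with 8867 probe sets, exchanged only 2 of 18 arrays and so kept most of the species difference.

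For the comparisons with 0 calls in limma every split gives as many by construction, so these counts decide nothing: 100 of 100 for SM, GR and their interactions (highest other 38, for SM against GR over both carriers), 35 of 35 for GR against backbone on MAP4 and 84 of 84 for it in the 4.x series (highest other 135). For small p-values chance can be excluded for SM against backbone over both carriers (1 of 100 splits with as many as 1784, highest other 1696), although the count was 189 without MAP8 backbone replicate 1. For SM against GR 4 of 100 had as many as 1636 (highest other 2005), too close to the limit of 0.05 to exclude chance. Nor is chance excluded for GR against backbone over both carriers (89 of 100 with as many as 109, highest other 1459). These shares were not adjusted for the number of comparisons. For calls, chance is not excluded for PBS against unimmunized rabbits (6 of 56 splits, 1 against 8), for immunized rabbits against PBS in the 4.x series (7 of 100, 1 against 5) or for SM against GR there (6 of 100, 5 against 53), where the share lay close to the limit and an earlier draw of splits fell on its other side. Splits that call several times the real count point to a structure of the samples, which was not tested. For backbone against PBS the 10 splits are too few for a share under 0.05 (10 of 10, with 0 against 1).

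SM against backbone in the 4.x series gave 11 calls, and only the real one of 35 splits gave as many (highest other 3). The comparison and this test were chosen after the result was seen. The share was also not adjusted for the number of comparisons. Chance is therefore not excluded for these calls, nor for the 1460 small p-values (3 of 35 splits with as many, highest other 1509). The count of calls ranged from 0 to 22 when single arrays were left out and was 0 with sex as a factor (1398 with an unadjusted p under 0.05 in limma). If these calls reflect an SM effect shared with cohort 2, their mean difference there, signed by the 4.x direction, would lie above 0. It was 0.04, and 38 of the 126 splits of the cohort 2 arrays gave as large a mean (exact one-sided permutation p = 0.30, highest other 0.18), so a shared effect may exist but was not detected.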
